A study of Homo sapiens with 6 samples.

How the data were processed

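The samples were 6 one-colour (Cy3) arrays of SKBR3 RNA, 3 from cells treated with 330 nM TSA for 24 h and 3 from PBS controls, grouped by the treatment named in the labels. Per the labels' protocols, ribosomal RNA was removed and the RNA was amplified and labelled by random priming along the transcript. Each scanner file held the intensity of 61184 spots, quantified with Agilent Feature Extraction 11.0.1.1 per the file headers. The processed signal is a background-subtracted and detrended intensity with no scaling between arrays, per the file headers and column names. The other columns used are raw spot and background intensity medians and flags, as deposited. A value table of 58944 probes, deposited by the authors, holds log2 values whose distributions are nearly identical between arrays. Its column medians are 6.79, and each column follows the log2 scanner signal of its array with a slope of 0.975 to 1.01 and a correlation of at least 0.9988. How the authors made it is not given in the sources used here. Its direction and log2 scale follow from this comparison. The headers give 1 scan time for all arrays, and 2 slides, with 4 arrays on slide 1 and 2 on slide 2.

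Control spots (1439), the 600 spots of 60 negative probes and outlier-flagged spots (147 to 199 per array) were left out. Spots of a probe were averaged on the log2 scale. The main values are log2 of the processed signal minus each array's 75th percentile over 58965 probes. A probe was tested if it was well above background on all 3 arrays of at least 1 group, with at least 2 values in each group, which left 43651 probes. For a probe not well above background on any array of a group, the fold is given as at least the bright group's mean over the dim group's mean, each dim array taken at the higher of the probe's own signal and the lowest signal of a probe well above background.

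TSA was compared with PBS by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probes tested, at an adjusted p of 0.05 and, where stated, a fold of 2. If the arrays of a group do not come from separate cultures, the p-values measure only technical spread. The procedure was tested on simulated data for this comparison with 43651 probes, of which 50 each were changed by 1, 1.5, 2 and 3 on the log2 scale. It recovered 34%, 60%, 86% and 84% of them, with 6 false calls in all. The simulated noise was independent between probes, and far fewer probes were changed than the 13554 called in the data. These rates therefore need not hold for the real comparison.

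Gene names came from the RefSeq accession of a probe, matched without versions to the RefSeq gene table of assembly GRCh38.p14. All 20 probes with an accession matched. The other 58945 probes carry identifiers that the files used here do not pair with genes or with a coding or non-coding class. No coordinates are given, since the headers name another build. The rule for named genes, fixed before the data were examined, took the 12 highest and 12 lowest coding genes past the threshold without overlap of the groups, 6 and 6 non-coding genes, members of 48 gene lists and a set of fixed genes. As only 20 genes could be named, these are reported in full except for 2 that are not reported here, with the 2 highest and 2 lowest other probes by the same rule. The comparison of non-coding with coding probes and the tests of gene lists, which needed at least 5 measured members, were therefore not made.

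Alternatives fixed beforehand were normexp background correction (offset 50) with the 75th percentile or quantile normalization, quantile normalization alone, the median of tested probes, the 75th percentile of probes detected on all arrays, the authors' value table, no filter, a filter on all 6 arrays, a block for the replicate number or the slide, eBayes with trend and robust, array weights, each replicate left out, a fold of 1.5, and a less strict detection flag. Normexp used the median spot signal, as the files used here have no mean signal. The comparison within slide 1 was added after the data were seen. For the share of changes among probes with room for a fall, a probe counted if it was well above background on all PBS arrays with a PBS level at least 4-fold over the 95th percentile of probes not well above background. Differences of single measures between groups were tested with a two-sided exact permutation test, whose smallest p is 0.1 with 3 arrays per group.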

Results

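RNA from SKBR3 cells was hybridised to 6 one-colour Agilent arrays, 3 from cells treated with 330 nM TSA and 3 from cells given PBS. SKBR3 is a human breast cancer line with an amplified ERBB2 gene. TSA is taken here to be trichostatin A, an inhibitor of histone deacetylases, since the labels give only the abbreviation. The treated cells were measured at 24 h, and the labels describe the 3 samples of a group as independent experiments. They also speak of different donors, although every sample is of the same line, so what separates the replicates is not settled. Between 70.2% and 78.5% of the 58965 probes were well above background on a given array, and 66.4% were so on all 6. The 75th percentile of the signal ran from 479 to 718 intensity units. No spot was saturated. The number of arrays, 3 per group, limits the precision of every comparison.

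The question was which transcripts differ in level between treated and control cells. Gene names are given for 18 genes, each read from 1 probe printed as 10 spots and carrying a RefSeq accession. Control probes for GAPDH and PGK1 are also on the arrays, but the levels below do not use them. Unnamed probes of the same genes could not be recognised. Nearly all other probes have only a supplier's identifier, so the wider response is described below by counts of probes. None of the other genes set out for naming beforehand, among them the histone deacetylases and ERBB2, could be read from these arrays.

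MTX1, a component of the mitochondrial outer membrane involved in protein import, fell 2.80-fold in TSA. Its level was 6.54 ± 0.50 (SD, n = 3) in PBS and 5.05 ± 0.04 (SD, n = 3) in TSA, on the log2 scale relative to each array's 75th percentile. ARHGDIA fell 2.05-fold. PGK1, a glycolytic kinase, fell 1.77-fold. ODC1, the rate-limiting enzyme of polyamine synthesis, rose 2.80-fold, from 4.83 ± 0.07 to 6.31 ± 0.05 (SD, n = 3 each). GRM4, a metabotropic glutamate receptor gene with a dim signal in both groups (69.2 units in PBS and 113 in TSA), rose 1.36-fold.

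These 5 of the 18 named genes passed limma's test at an adjusted p under 0.05, and 3 of them changed at least 2-fold. The number at least 2-fold was 2 with quantile normalization, with or without normexp, and with the 75th percentile of probes detected on all arrays, where ARHGDIA stood at -0.82, -0.82 and -0.98. It was 6 without PBS control replicate 1 and 1 with the slide as a block. The log2 difference, TSA minus PBS, was -1.49 for MTX1 (SE 0.25, adjusted p = 0.00526), -1.04 for ARHGDIA (SE 0.24, adjusted p = 0.0189) and -0.83 for PGK1 (SE 0.11, adjusted p = 0.00223). It was 1.48 for ODC1 (SE 0.11, adjusted p = 0.000194) and 0.45 for GRM4 (SE 0.12, adjusted p = 0.0348). For 8 of the 18 genes the 3 TSA values and the 3 PBS values did not overlap, where chance gives 10% for a single gene. The genes share the scaling of each array and are not independent. The share without overlap over all tested probes is not given here, so the 8 do not set these genes apart. Of all tested probes, 31.1% passed limma's test. ODC1 passed in each of the 18 alternative settings and MTX1 in 16, while GRM4 passed in only 5 and ARHGDIA in 12. The call of ARHGDIA ended without PBS control replicate 3 (adjusted p = 0.0666) and without each TSA replicate (0.0556 to 0.0637), and its adjusted p ranged from 8.01e-05 to 0.237 over all its alternatives. That of GRM4 ended without PBS control replicate 2 or 3 and without each TSA replicate (0.0583 to 0.127). The log2 difference of GRM4 was only 0.15 with normexp and the 75th percentile, and 0.18 with normexp and quantile normalization.

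**Figure D1:**
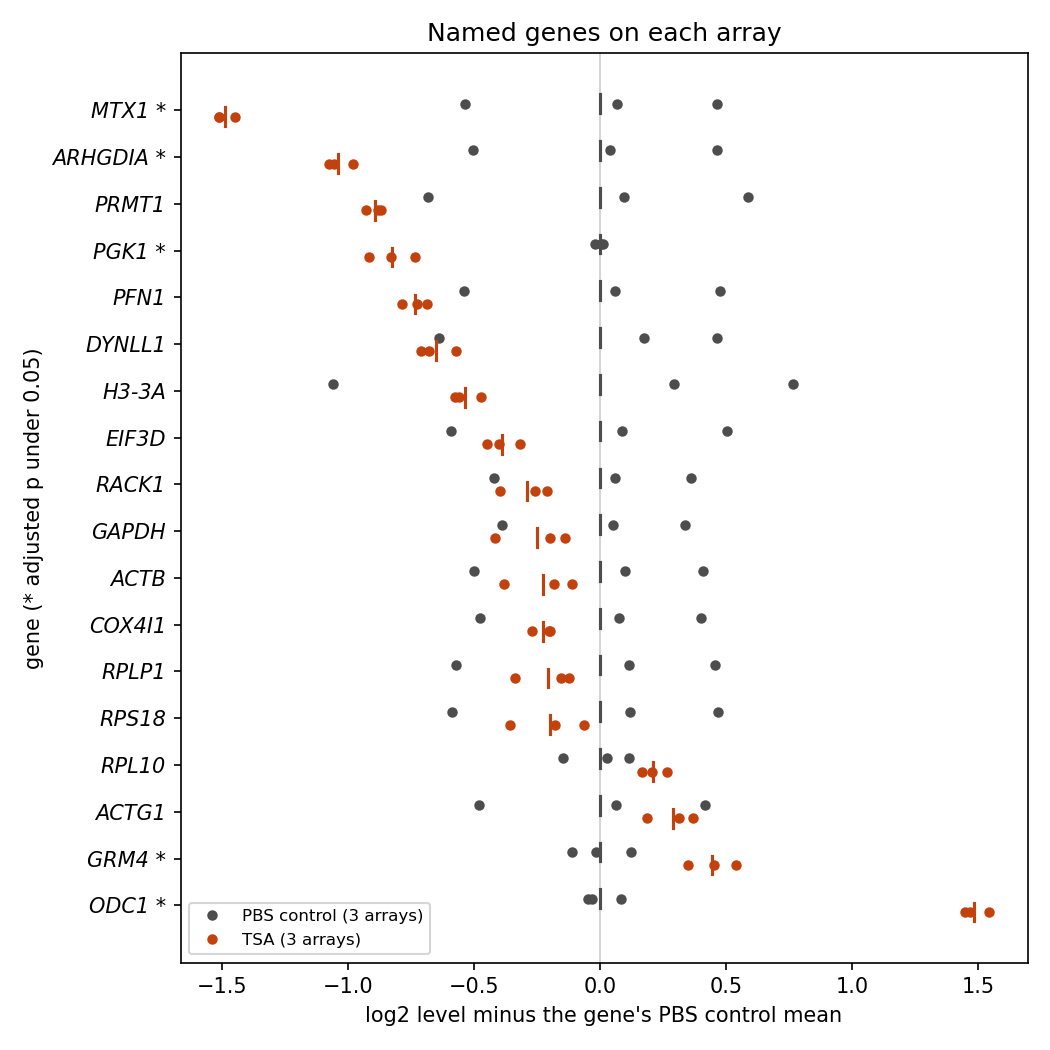
Level of the 18 named genes on each array, as the log2 value minus the gene's mean over the PBS control arrays. Points are single arrays, short vertical lines are group means (n = 3 per group), and an asterisk marks an adjusted p under 0.05. The TSA arrays lie within a narrow span for each gene, and most genes with bright signals spread more widely over the PBS arrays. Part of that wider spread comes with the scaling.

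The other 13 named genes did not pass the test. PRMT1, the main protein arginine methyltransferase, had a log2 difference of -0.89 (SE 0.30, adjusted p = 0.0674), and PFN1, which encodes the actin-binding protein profilin, one of -0.73 (SE 0.25, adjusted p = 0.0689). DYNLL1, a dynein light chain gene, had a difference of -0.65 (SE 0.28, adjusted p = 0.124). With quantile normalization these 3 genes and ACTG1 passed (ACTG1 0.50, adjusted p = 0.0158, range over its alternatives 0.00494 to 0.839). The adjusted p under quantile normalization was 0.016 for PRMT1 (range 0.000308 to 0.394), 0.00803 for PFN1 (range 0.000366 to 0.384) and 0.0202 for DYNLL1 (range 0.000486 to 0.473). GRM4 did not pass with that scaling (0.0684, range 0.000432 to 0.31). Without PBS control replicate 1, PRMT1, PFN1, DYNLL1, H3-3A, EIF3D and RACK1 all passed, with log2 differences from -1.23 for PRMT1 to -0.50 for RACK1 and adjusted p between 0.00427 and 0.044.

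The reference genes GAPDH and ACTB were among the brightest on the arrays. GAPDH stood at 427300 units in PBS and 430100 in TSA, and ACTB at 432400 and 443400. Their scaled log2 differences were -0.25 for GAPDH (SE 0.20, adjusted p = 0.394) and -0.22 for ACTB (SE 0.24, adjusted p = 0.515). The value of ACTB turned to 0.01 with quantile normalization, as those of COX4I1, RPLP1 and RPS18 also turned slightly above 0 there, so no direction is given for these 4. With array weights, however, GAPDH (-0.41, adjusted p = 0.00772, range over its alternatives 0.00772 to 0.958) and ACTB (-0.42, adjusted p = 0.00989, range 0.00989 to 0.944) passed as lower. So did COX4I1, RPLP1, RPS18 and H3-3A (adjusted p from 0.00373 to 0.0157). That fit called 26713 of the 43651 tested probes and rested mainly on PBS control replicate 3 (weight 9.48) and TSA 1 (3.71). The other weights were 0.232 to 0.796. Before scaling, GAPDH stood at 401600 units on that PBS array and 416300 on TSA 1, and ACTB at 420300 and 432300. Of the gene lists drawn up beforehand, 5 held any named gene and none held the 5 members needed for a test. The housekeeping reference list held 3 of the genes, of which PGK1 fell and GAPDH and ACTB did not pass in the main comparison. PGK1 and GAPDH were also the only members read from the glycolysis and hypoxia list. The variant histone list held H3-3A alone (-0.53, adjusted p = 0.396), the oxidative phosphorylation list COX4I1 alone (-0.22, adjusted p = 0.491) and the cytosolic ribosomal protein list RPLP1 alone (-0.20, adjusted p = 0.589). RPS18 (-0.20, adjusted p = 0.614) and RPL10 (0.21, adjusted p = 0.235) were measured too but are not on that list as drawn up. RPL10 was dim, at 267 units in PBS and 371 in TSA.

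Across all probes, 13554 of the 43651 tested (31.1%) differed between TSA and PBS at an adjusted p under 0.05 in limma. Of these, 7021 were higher in TSA and 6533 were lower. That order turned with normexp and the 75th percentile (5983 higher, 8013 lower), with median scaling (6405 and 7789), with array weights (12111 and 14602) and among probes well above background on all 6 arrays (5505 and 6307), so neither direction is given as the more frequent. The lower probes numbered 3007 without PBS control replicate 3, and 4246, 3702 and 3914 without TSA replicates 1, 2 and 3. At least 2-fold differences were found for 5858 probes, 3958 higher and 1900 lower. Normexp with the 75th percentile gave 3088 (1919 higher, 1169 lower), and without TSA replicate 2 the lower probes numbered 1229. At least 4-fold, 1452 probes were higher and 210 lower. These folds include signals not well above background. Among called probes well above background on all 6 arrays, 2576 were at least 2-fold higher and 1647 lower, and 634 and 154 at least 4-fold. Among the 31175 probes whose PBS level lay at least 4-fold above dim signals, 1642 were at least 2-fold higher and 1669 lower, and 333 and 191 at least 4-fold. From 16-fold upwards, 166 of all tested probes were higher and 2 lower, against 31 and 1 of those well above background on all 6 arrays and 7 and 2 of those with that PBS level. The highest rise under the naming rule was that of probe ASHGA5P055387, by 335-fold (log2 difference 8.39, SE 0.14, adjusted p = 5.55e-06), though the log2 difference was 6.77 with normexp and the 75th percentile. Probe ASHGA5P039044 was not well above background on any PBS array and rose at least 43.2-fold (adjusted p = 1.88e-05), with a log2 difference of 3.92 under that alternative, whose offset shrinks differences of dim probes. Probe ASHGA5P048563 fell 16.2-fold (log2 difference -4.01, SE 0.40, adjusted p = 0.000605). Probe ASHGA5P027407 was well above background on only 1 of the 3 TSA arrays, so the size of its fall is not known (adjusted p = 0.0488). TSA 1 stood at 0.05 there, against a PBS mean of 1.30, a log2 difference of -1.25 within slide 1, and the call ended in 10 of 18 alternatives, among them those without each PBS replicate (adjusted p 0.0854 to 0.12) and without TSA replicate 2 (0.15) or 3 (0.139).

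The file headers place the 3 PBS arrays and TSA 1 on slide 1 and TSA 2 and TSA 3 on slide 2. With the slide as a block, 4075 probes passed (3096 higher and 979 lower). As slide 2 holds no PBS array, the difference in that fit comes from TSA 1 alone, with TSA 2 and TSA 3 adding only to the estimate of spread. The fit is therefore no separate check from that within slide 1. Within slide 1 alone, where TSA 1 is assumed to vary like the PBS arrays, 1969 passed (1702 higher and 267 lower). No comparison can be made within slide 2, which holds TSA arrays only. ODC1 passed with the slide as a block, and MTX1 (adjusted p = 0.0637), ARHGDIA (0.142), PGK1 (0.0549) and GRM4 (0.265) did not, at log2 differences of -1.51, -1.08, -0.83 and 0.45. ODC1 alone of the 18 passed within slide 1 (adjusted p = 0.036, range over its alternatives 1.67e-06 to 0.036). Without PBS control replicate 3, 8033 probes passed.

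**Figure D2:**
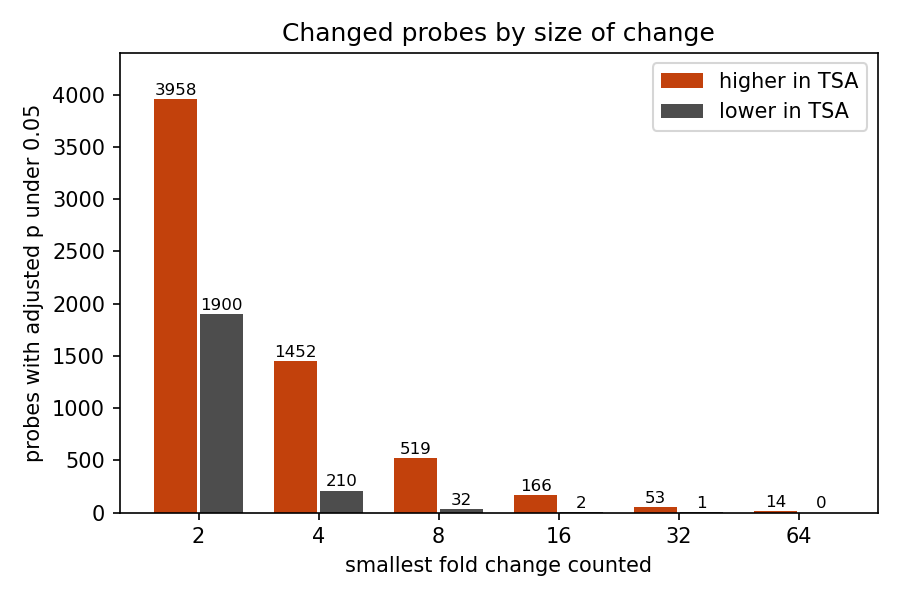
Number of probes with an adjusted p under 0.05, counted from the fold change on the horizontal axis upwards, for probes higher and lower in TSA. Probes higher in TSA number 3958 and those lower 1900 from 2-fold upwards, with folds against signals not well above background included.

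The split between higher and lower probes depended on the brightness of the probes. The tested probes were divided into 5 groups of equal size by mean signal. In the dimmest group 1370 were at least 2-fold higher in TSA and 267 were lower. In the middle group the numbers were 821 and 367. In the brightest group they were 300 and 509, and this order turned with quantile normalization, to 417 higher and 309 lower. The median log2 difference of all tested probes also shifted with brightness, from 0.04 in the dimmest group to -0.18 in the brightest. A dim probe could be tested through the arrays where it was high, and had little room to fall.

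In total 881 probes were well above background on all 3 TSA arrays and on none of the PBS arrays, and 71 showed the opposite. With the less strict detection flag the numbers were 403 and 73. Of the 881 probes, 779 were at least 2-fold higher at an adjusted p under 0.05 in limma, and of the 71, 50 were at least 2-fold lower. Both kinds of count come from the same arrays, so the overlap is no separate support. The control arrays differed in how many probes they detected, and without PBS control replicate 1, which detected 78.5%, the number rose from 881 to 1777. Against that array TSA 1 gained 1736 probes and lost 2438, whereas against PBS control replicate 2, which detected 70.2%, it gained 4729 and lost 544. The number detected in PBS only was 71 and rose to 180 without PBS control replicate 2, 155 without PBS control replicate 3, 261 without TSA replicate 1 and 130 without TSA replicate 3.

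The arrays separated by group. The first principal component, 72.1% of the variance over tested probes, put the PBS arrays between -88.4 and -87.7 and the TSA arrays at 74.3, 96.1 and 93.7. Correlations across probes were 0.975 to 0.990 within a group and 0.932 to 0.956 between groups, where probes are not independent replicates. At least 2-fold, 4260 probes differed between PBS control replicates 1 and 2, and 1241 to 1520 in the other pairs within a group. Between groups the number was 5747 to 9383. The second component, 14.1% of the variance, placed PBS control replicate 1 at 67.3 and replicate 2 at -65.9. Most bright named genes spread over the PBS arrays, lowest on replicate 1 and highest on replicate 2. ODC1 had an SD of only 0.071 there. Scaled PRMT1 values had an SD of 0.64 over the PBS arrays and 0.03 over the TSA arrays. Those of H3-3A had SDs of 0.95 and 0.05. Part of the PBS spread came with the scaling, as the 75th percentile was 700, 479 and 501 units on replicates 1, 2 and 3. Unscaled GAPDH signals there were 414600, 468500 and 401600 units, against scaled values of 9.21, 9.93 and 9.65. H3-3A still ran from 66060 to 160000 units before scaling. The difference between 5' and 3' control probes for GAPDH, a measure of RNA integrity and labelling, was -1.37 ± 0.28 in PBS and -1.40 ± 0.12 in TSA (SD, n = 3 each, exact permutation p = 1, two-sided, smallest possible 0.1). For PGK1 the difference was much larger, at -6.07 ± 0.47 in PBS and -6.10 ± 0.17 in TSA (log2 scale, SD, n = 3 each).

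TSA 1 stood apart from the other two TSA arrays in part of the falling probes. Among 275 probes at least 4-fold below PBS in both TSA 2 and TSA 3, 208 (75.6%) were less than 2.83-fold lower in TSA 1. Chosen in the same way, only 1 of 56 probes stood out in TSA 2 and 2 of 75 in TSA 3. Among the 1314 probes at least 4-fold above PBS in TSA 2 and TSA 3, 4 were less than 2.83-fold higher in TSA 1. In the set of 208 the median log2 difference from PBS was -0.89 in TSA 1, -2.95 in TSA 2 and -2.67 in TSA 3. Of these 208 probes, 187 count among the 1900 that fell at least 2-fold, and 5 did within slide 1 alone.

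**Figure D3:**
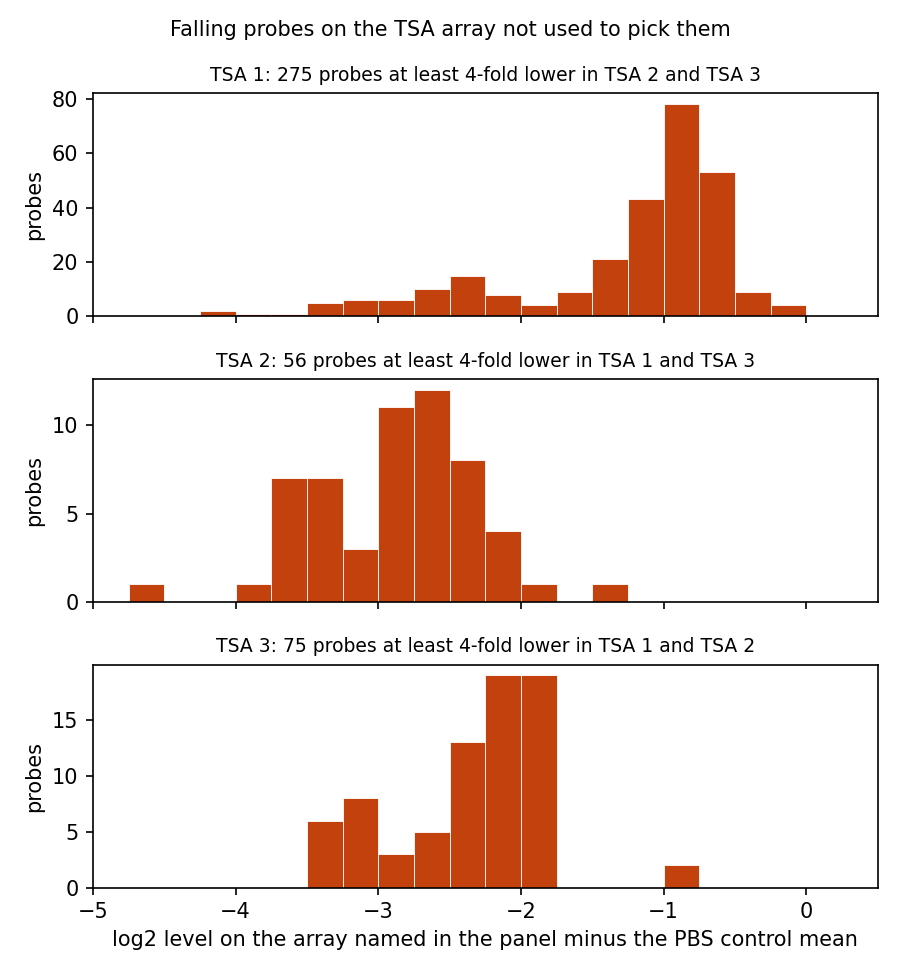
Probes at least 4-fold below the PBS control mean on both other TSA arrays, by their log2 difference from the PBS control mean on the TSA array named in each panel. The height of a bar is the number of probes. In TSA 1 the median of 275 probes was -0.99, against -2.80 of 56 probes in TSA 2 and -2.22 of 75 probes in TSA 3.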

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

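The comparison within slide 1 alone was chosen after the data were seen, and the other settings beforehand. Of the settings for the 18 named genes and 4 named probes, 327 kept direction and side of the threshold, 33 lost the call, 28 gained one and 10 changed sign without a call in either setting. The means of several probes per gene, the set tests and the coding comparison were not run. Each named gene has only 1 probe with an accession, and no list reached the size for a test. The authors' value table lacks the named genes. The cause of the shifts below was not tested unless stated.

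The replicate number as a block gave 12179 changed probes, 5930 at least 2-fold and 3 genes at least 2-fold. No pairing of the arrays by number was visible, though 3 arrays per group cannot exclude it. Deviations of arrays with the same number correlated at 0.03, 0.18 and 0.06 across probes, and only 2 of 6 arrays correlated best with their own number.

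The slide as a block left 4075 probes changed (3096 higher, 979 lower), 3755 at least 2-fold (807 lower) and 1 gene at least 2-fold. In this fit the difference comes from TSA 1 alone. Slide 1 alone, with fewer arrays, left 1969 (1702 higher, 267 lower), every one at least 2-fold, and 1 gene; 1964 of these were among the 5858. Array weights raised the changed probes to 26713 (12111 higher, 14602 lower), with weights from 0.232 for PBS control replicate 1 to 9.48 for PBS control replicate 3. Normexp, whose offset shrinks differences of dim probes, gave 3088 probes at least 2-fold (1919 higher, 1169 lower), or 3105 with quantile normalization (2113 and 992). The filter on all 6 arrays, which removes probes dim in 1 group, left 2580 at least 2-fold higher. A fold of 1.5 gave 10995 (6106 higher, 4889 lower).

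With each replicate left out, changed probes ranged from 8033 (without PBS control replicate 3) to 14678, higher ones from 5026 to 7637 and lower ones from 3007 to 7041, where leaving out each TSA replicate also gave fewer (4246, 3702 and 3914). Those at least 2-fold ranged from 4948 to 6123, higher ones from 3645 to 4120 and lower ones from 1229 (without TSA replicate 2) to 2222. Genes at least 2-fold ranged from 2 to 6 (without PBS control replicate 1). Probes detected in TSA only ranged from 923 to 1777 and those in PBS only from 81 to 261. With the less strict flag 403 were detected in TSA only, and within slide 1 alone 1471 in TSA only and 183 in PBS only.

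Dim signal limits what can be read. On PBS control replicate 1, 24.2% of negative probe spots were well above background, and 12.8% to 18.5% were on the other arrays.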

Other observations

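The tests of scaling, of the slide, of probes with room below, of the falling probes of TSA 1 and of the splits were chosen after the results they bear on had been seen. The test on probes well above background on all 6 arrays was chosen beforehand.

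More probes rose than fell at least 2-fold (67.6% of the 5858 calls were higher). The lowest share over 6 scalings was 61.7%, so the choice among these scalings does not account for the excess. All 6 set the arrays to a common level or distribution. A shift common to the probes of 1 group would not show in them, so scaling as an account is not settled. Among probes well above background on all 6 arrays the share was 60.9%, within counting error of the limit of 60% set beforehand, and among the 31175 probes with room to fall 1642 were at least 2-fold higher and 1669 lower, so at 2-fold the excess and the background floor cannot be told apart. At least 4-fold, 333 of those probes were higher and 191 lower (63.5% higher), which the floor alone would not give. These counts rest on the mean of the 3 TSA arrays, and TSA 1 lacks part of the falls. Of tested probes, 82 were 4-fold lower in TSA 1, against 494 in TSA 2 and 506 in TSA 3. The counts of 333 and 191 were not repeated without TSA 1, so its part in this excess is not known. The share within slide 1 was 86.4%, but it rests on TSA 1, which lacks part of the falls, so a difference between the slides stays open, as does an effect of the treatment, which was not tested apart from these.

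The 208 probes at least 4-fold below PBS in TSA 2 and TSA 3 but not in TSA 1 were set against 3 accounts. Failure of these probes on slide 2 as the sole cause is argued against by TSA 1, which lay below all 3 PBS arrays at 94.2% of them, compared with 37.4% of all tested probes. PBS RNA mixed into TSA 1 would have lowered the rising probes too, yet over 1314 rising probes the median of TSA 1 minus TSA 2 and TSA 3 was -0.0095 on the log2 scale. A first test, the number of probes 4-fold lower in TSA 1 (82), decided nothing, since 1 PBS array had 81 against the other two. A single RNA source reduced to a fixed proportion in TSA 1 was not decided, since over all 275 probes chosen by TSA 2 and TSA 3 the robust SD of TSA 1 minus PBS was 0.40 on the log2 scale, between the limits for and against it. TSA 1 is also the only TSA array on slide 1, so a difference between treated cultures and an added effect of the slide stay open.

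In 1 of 10 splits of the 6 arrays, the real one, limma called 13554 probes, 5858 of them at least 2-fold, and the highest of the other splits gave 0 in both counts. For probes detected in 1 group only, the real split gave 952 and the highest of the others 404, again 1 of 10 splits. With 10 splits no share under 0.05 can be reached. At an unadjusted p under 0.05 the real split gave 18279 probes and the highest of the others 1219. Every other split puts TSA and PBS arrays in the same group. A difference between the treatments then adds to the spread within groups and lowers these counts. The other splits therefore do not show how many calls would arise without a difference.

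Of 128 control and negative probes, 2 were higher on all TSA arrays than on all PBS arrays. The number in the opposite order and the number expected by chance are not given here, so nothing is concluded from this count.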
